A study of Mus musculus with 35 samples.

How the data were processed

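Total RNA of sorted mouse bone marrow LT-HSCs was sequenced in bulk. Per the labels' protocols, cells were sorted into lysis buffer, RNA was extracted with a nanoscale kit and barcoded libraries were made. For the knockdown, cells were kept on fibronectin with TPO and SCF, and the labels give 1 µg/mL doxycycline in the growth protocol and 1.5 µg/mL in the treatment protocol without saying which applied, and carry the same protocol text on the reporter samples. The authors deposited 2 tables of raw read counts per gene, 1 for each experiment. Per the file headers, the reads were counted with featureCounts 1.5.3 over exons, summed per gene, with strand setting 1, which counts sense reads only. Per the submitters' processing notes, reads were aligned with STAR to mm10 and DESeq2 was used. The version of STAR is not given in the sources used here. The values are whole numbers whose totals differ between libraries. Whether the library kit marks strand is not given in the sources used here. The header of the knockdown table lists 33 alignments and the table holds 23 columns; the other 10 are not analysed here. Each table has 24435 genes and no line without a gene. Gene symbols were used as the tables give them: 96.7% matched a name in the mouse gene name tables used, 27 had the form of spreadsheet dates and were never named, and 13 mitochondrial genes were named through the RefSeq gene table. Counting by gene means that overlapping entries, such as Cux1 and Casp, and near-identical copies, such as ribosomal protein pseudogenes, can share or lose reads.

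Groups were taken from the sample titles, as fraction and hairpin, with the replicate letter. The 2 tables were fitted separately because they were separate experiments. Library totals ranged from 24384767 to 35729310 counts (reporter) and from 30922857 to 74811655 (knockdown). Genes were kept with edgeR's filterByExpr, which left 13941 and 14548 genes, and library sizes were scaled by TMM. Each gene was tested with edgeR's quasi-likelihood F test (version 4.0.16, R 4.3.3) with 1 coefficient per group over all libraries of the table. The biological coefficient of variation was 0.297 in the reporter and 0.211 in the knockdown experiment. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. Comparisons were Bright with Dim, Int with Dim and Bright with Int in the reporter experiment. In the knockdown experiment they were shCUX1 with shControl averaged over the 3 fractions and in each fraction, the difference of that effect between Bright and Dim, and Bright with Dim among shControl libraries. Levels are CPM on TMM-scaled library sizes, and log2 CPM used a prior count of 2.

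Cux1 and Casp, as well as the signature score, were also compared with two-sided permutation tests on the absolute difference of group means, exact where a group had fewer than 10 libraries and with 100000 resamples for the mean knockdown effect. With 4 libraries against 4, or 4 against 3, the smallest exact p is 0.0286. Gene lists, 30 in all, covered stem cell identity, cell cycle, lineages, other cell types of bone marrow, stress, metabolism and RNA quality. They were tested with camera (limma 3.58.1, called through edgeR) at a preset correlation of 0.01 between genes, adjusted over the 30 lists. Camera with an estimated correlation and fry, which does not compare a list with other genes, served as alternatives. The reporter signature was tested with fry, with genes weighted by their direction, and its p was adjusted over the 6 knockdown-experiment comparisons. The overlap of called genes used Fisher's exact test.

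These comparisons, tests, lists, most of the alternatives and the rule for named genes were fixed before the data were examined. The rule took Cux1 in every comparison and, in the 3 main comparisons, the 10 genes with the largest fold change in each direction among called genes with a mean log2 CPM of at least 2. It also required no overlap between the libraries of the 2 groups (for the mean knockdown effect, the same sign in all 3 fractions), and left out predicted genes and pseudogenes. Other comparisons took 5 in each direction, and all called genes where fewer than 5 were called. Up to 4 members of smallest p were added from each described list. Levels of Mki67, Procr and Vwf were chosen for printing after the fold changes were seen.

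The same code was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. For reporter Bright against Dim it recovered 7.46%, 46.3% and 81.8% of genes changed 1.5, 2 and 4-fold, with 4 unchanged genes called. For the mean knockdown effect it recovered 73.1%, 85.1% and 95.5%, with 15 unchanged genes called. For knockdown in Dim the shares were 44.8%, 68.7% and 83.3% with 7 such calls, and for cultured Bright against Dim 49.3%, 71.6% and 83.3% with 10. The cut-off of an adjusted p depends on how many genes differ. These shares therefore cannot tell how many changes the real comparisons missed, knockdown in Dim included.

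Replicates were checked before averaging. Counts of the 51 pairs of libraries within a group differed by a chi-square of 23.8 to 243 per gene, so no pair was a repeat of 1 library. Xist and Y-linked counts showed that a letter had the same sex in every group of an experiment: reporter letters A and D had 10305 to 16171 Xist counts and at most 99 Y-linked counts, and B and C had at most 48 Xist counts and 4128 to 8406 Y-linked counts. Knockdown letters A and B had 4101 to 10257 Xist counts, and C and D had 7855 to 13047 Y-linked counts. The labels do not say that a letter marks a shared animal or day. Libraries of the same letter deviated together from their group means, with every correlation over 0.1, only for Bright shControl with Bright shCUX1 (0.211 to 0.371) and Dim shControl with Bright shControl (0.221 to 0.347). The letter is therefore a hint of pairing from the data, and was fitted as a block as an alternative.

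Alternatives fixed beforehand were DESeq2 size factors or upper-quartile scaling in place of TMM, no filter or a mean count of at least 50, DESeq2 (version 1.42.0) or limma voom with quality weights in place of edgeR, a test against a fold of 1.2, a fit of the compared groups alone, the letter as a block, other signature genes, and each library left out in turn. Chosen after the data were seen were fits without the libraries that stood apart (Dim B and Bright C in the reporter experiment, Dim shCUX1 B and Bright shControl D in the knockdown experiment) and the removal of each library's linear trend of log2 CPM on log2 gene length before a limma fit. So was a test of the score differences within letters over all sign flips. A library's length slope is that of its deviation from the mean of the other libraries of its group on log2 gene length, over genes with a mean log2 CPM over 1. No fixed rule picked the libraries that stood apart. This slope was -0.21 in Dim B, -0.44 in Bright C and -0.26 in Dim shCUX1 B. Bright shControl D had the fewest genes with a count in its experiment (13957). Int shControl A, with a slope of -0.18, was kept in these fits. Also chosen afterwards was a search of all 16322 heptamers found in at least 30 genes in the 3' UTRs of genes lower after knockdown, against the other tested genes. The longest annotated 3' UTR per gene (GENCODE vM21 transcripts, at least 50 bases) was used, and the test was an exact one-sided hypergeometric test within 5 classes of 3' UTR length, then within classes of length and A content. Permutation and Fisher's tests were run in R. The heptamer search was run in Python 3.11.15 with scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.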

Results

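Bulk RNA sequencing was carried out on long-term haematopoietic stem cells (LT-HSCs), the bone marrow cells that sustain blood formation over the life of an animal, from mice with an mCherry reporter on both copies of Cux1. CUX1 is a homeodomain transcription factor. The cells were sorted by reporter level into the fractions named Dim, Int and Bright. The reporter experiment had 12 libraries, 4 of each fraction, with the replicate letters A to D. The knockdown experiment had 23 libraries from the same 3 fractions, in which a control hairpin (shControl) or a hairpin against CUX1 (shCUX1) was induced with doxycycline for 3 days outside the animal, in a stem cell medium with the cytokines TPO and SCF. Each of its 6 groups had 4 libraries except Dim shControl, which had 3 (A, C and D). Counted reads per library ranged from 24384767 to 35729310 in the reporter experiment and from 30922857 to 74811655 in the knockdown experiment. The labels do not state that the replicates were separate animals or cultures, so each p-value measures the spread between these libraries, which may be technical in part. Xist and Y-linked counts showed female and male libraries in every group, so no group came from a single animal. An error given after a log2 fold change is its standard error. An error given after a level in counts-per-million (CPM) is the SD over the libraries of a group. Genes named for the size of their change are those that met the rule for named genes, which asks for a mean log2 CPM of at least 2 and, between 2 groups, no overlap of their libraries, so a gene outside it can have changed further. The words "rose" and "fell" are used for changes past a Benjamini-Hochberg adjusted p of 0.05.

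The targeted gene was examined first. Cux1 lies on chromosome 5 of mm10, from 136266410 to 136567490 on the minus strand. It shares 2107 of its 13820 exon bases with Casp, which was counted as a separate gene. Casp lies on the same strand and its 5' end lies at the same base. Reads in the shared bases cannot be told apart, so both values are uncertain to that extent. In all 12 shCUX1 libraries Cux1 was between 10.1 and 42.5 CPM, below all 11 shControl libraries, which lay between 58.9 and 95.0 CPM. In each fraction the highest shCUX1 level was that of letter D. It was 42 CPM in Dim, 37 in Int and 39 in Bright, against 59, 81 and 84 CPM with shControl in that letter. Averaged over the 3 fractions, Cux1 fell 3.16-fold (log2 fold change -1.66 ± 0.18, edgeR adjusted p = 7.83e-05; permutation p = 1e-05, two-sided and the smallest that 100000 resamples can give). By fraction, the level fell from 86.3 ± 6.58 to 25.2 ± 9.58 CPM in Bright (n = 4 and 4, edgeR adjusted p = 0.0289; exact permutation p = 0.0286, the smallest possible). In Int it was 78.3 ± 7.71 CPM with shControl and 24.7 ± 9.26 with shCUX1 (n = 4 and 4, edgeR adjusted p = 0.0567; exact permutation p = 0.0286). The Dim groups had 73.1 ± 13.0 CPM with shControl (n = 3) and 25.2 ± 13.3 CPM with shCUX1 (n = 4), at an edgeR adjusted p = 0.408 and an exact permutation p = 0.0571. Casp did not pass the test after knockdown (log2 fold change -0.06 ± 0.06, edgeR adjusted p = 0.758).

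In the reporter experiment, Cux1 RNA was higher on average in Int and Bright than in Dim, but no difference between fractions passed the test. The means were 141 ± 73.5 CPM in Dim, 197 ± 72.9 in Int and 217 ± 102 in Bright (n = 4 each), and single libraries ranged from 44.8 to 213 CPM in Dim and from 107 to 348 CPM in Bright. The log2 fold change of Bright over Dim was 0.62 ± 0.43 (edgeR adjusted p = 0.282, two-sided exact permutation p = 0.371), and that of Int over Dim was 0.48 ± 0.43 (edgeR adjusted p = 0.565, exact permutation p = 0.343). These tests did not use the letters. For letters A to D, Cux1 was at 180, 45, 126 and 213 CPM in Dim. It was at 212, 139, 143 and 294 CPM in Int, and at 234, 178, 107 and 348 CPM in Bright. Dim B and Bright C were among the libraries that stood apart. Casp rose from 56.6 ± 9.99 CPM in Dim to 106 ± 25.0 CPM in Bright (log2 fold change 0.91 ± 0.22, edgeR adjusted p = 0.00497, exact permutation p = 0.0286, n = 4 each). In the cultured shControl cells, Cux1 was 0.24 ± 0.33 log2 units higher in Bright than in Dim (edgeR adjusted p = 0.647; exact permutation p = 0.143, n = 4 and 3).

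**Figure D1:**
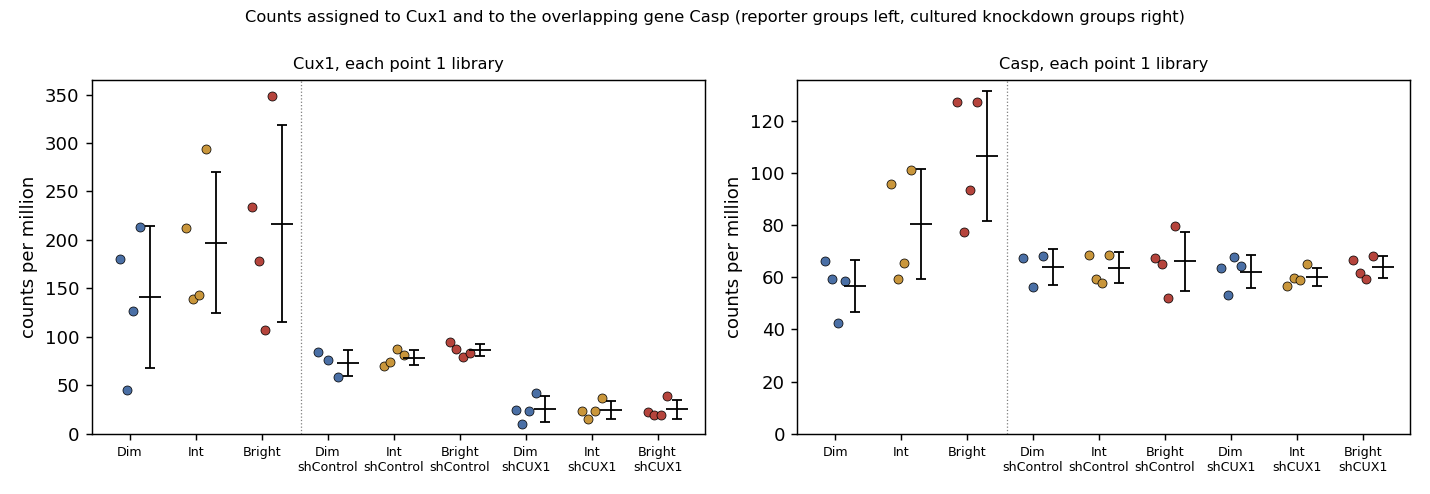
Cux1 level in CPM in each library of the reporter experiment (3 groups of 4) and the knockdown experiment (6 groups of 3 or 4), with points for libraries and bars for the mean and SD of each group. The shCUX1 libraries lie between 10.1 and 42.5 CPM and the shControl libraries between 58.9 and 95.0 CPM, while the reporter fractions overlap.

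The comparison of Bright with Dim asked which genes went with the reporter level in LT-HSCs. Bright cells had far more RNA of cell cycle genes and less of the genes that mark the most primitive stem cells. All 28 measured genes of the G2/M and mitosis list rose, with a median log2 fold change of 4.18. Mki67, the proliferation marker, went from 20.0 ± 8.91 CPM in Dim through 81.6 ± 18.2 in Int to 520 ± 80.5 in Bright. At the other end Procr, the endothelial protein C receptor used to isolate stem cells, went from 206 ± 66.5 CPM in Dim through 80.9 ± 11.4 in Int to 31.6 ± 14.8 in Bright. Vwf, von Willebrand factor, went from 653 ± 286 through 134 ± 33.4 to 107 ± 40.8 CPM. Of 13941 genes tested, 5254 differed between Bright and Dim (edgeR quasi-likelihood test, adjusted p under 0.05), 2705 higher and 2549 lower in Bright (51.5% higher; 41.7% with upper-quartile scaling), and 2493 of them by more than 2-fold.

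Under the rule for named genes 10 genes were taken in each direction. Cep55, which acts in the last step of cell division (chromosome 19, 38055025 to 38074425), rose by 5.99 ± 0.54 log2 units (edgeR adjusted p = 2.48e-06). It was followed by Fam64a at 5.81 ± 0.37, the DNA glycosylase Neil3 at 5.73 ± 0.40, the mitotic ubiquitin-conjugating enzyme Ube2c at 5.66 ± 0.65 and Ankle1 at 5.53 ± 0.65. Pbk, Aunip, the kinase Aurkb, the kinetochore gene Nuf2 and the kinesin Kif18b rose by 5.16 to 5.45. Among fixed groups, 30 of 32 G1/S and replication genes rose and none fell (median 2.33), with Mcm5 at 2.36 ± 0.14, Tyms at 3.41 ± 0.21, E2f1 at 2.57 ± 0.16 and Cdc45 at 3.19 ± 0.20. Of 35 DNA repair genes 19 rose and none fell (median 0.48; 22 rose adjusted over the list alone), led by Rad51 at 3.82 ± 0.20, Chek1 at 2.72 ± 0.24, Brca1 at 3.51 ± 0.32 and Fanca at 2.24 ± 0.21. These 3 lists rose as sets with a preset correlation between genes (camera adjusted p = 2.12e-60, 5.06e-56 and 1.4e-09 for G2/M, G1/S and repair). They also passed with an estimated correlation (camera adjusted p = 0.0133, 0.00389 and 0.0159).

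Stem cell genes fell. Of 35 genes in the HSC identity list 27 fell and 1 rose (median -1.07), including Mllt3 at -2.27 ± 0.18, Sult1a1 at -3.68 ± 0.32, Fgd5 at -2.60 ± 0.24 and Robo4 at -1.75 ± 0.19 (list camera adjusted p = 1e-13; adjusted p = 0.00389 with an estimated correlation). HOX genes and their cofactors, which pattern the stem cell programme, fell in 11 of 20 cases and 1 rose (12 and 1 adjusted over the list alone; median -0.94, camera adjusted p = 7.43e-05), with Hoxb5 at -2.32 ± 0.27, Meis2 at -6.56 ± 0.93 and Hoxa5 at -1.63 ± 0.25. The HOX list had an adjusted p = 0.127 with an estimated correlation. The 10 lower genes taken by the rule for named genes included Smtnl1 (chromosome 2, 84811176 to 84822652) at -6.23 ± 0.43, the kinase Plk2 at -5.45 ± 0.34, the focal adhesion gene Tns2 (chromosome 15, 102102988 to 102116401) at -4.82 ± 0.18, Gimap3 at -4.68 ± 0.31 and the netrin receptor family gene Neo1 at -4.54 ± 0.50. They also included the interleukin-10 receptor chain Il10ra at -4.21 ± 0.52, Plekhg6 at -4.21 ± 0.38, the Wnt antagonist Sfrp1 at -4.15 ± 0.57, Gbp9 at -4.04 ± 0.46 and the ephrin Efna1 at -3.98 ± 0.40. Tns2 had the smallest adjusted p of the comparison, 6.24e-09.

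The quiescence list moved in both directions. Of its 27 genes 14 fell and 3 rose (median -0.53). The cell cycle inhibitor Cdkn1c fell by 2.28 ± 0.24 and Foxo1 fell by 1.40 ± 0.18, whereas Cdkn2c (4.00 ± 0.28) and the pocket protein gene Rbl1 (1.34 ± 0.14) rose. Its camera adjusted p was 0.035, and adjusted p = 0.449 with an estimated correlation. The call was lost without Bright D (adjusted p = 0.0683). Of 26 megakaryocyte and platelet genes 15 rose and 4 fell (16 and 4 adjusted over the list alone; median 0.69, camera adjusted p = 0.0222). Gp1bb (4.06 ± 0.37), the transcription factor Gata1 (3.56 ± 0.42) and Itga2b (2.44 ± 0.30) rose, while the thrombopoietin receptor gene Mpl (-0.94 ± 0.11) fell together with Vwf. That list had an adjusted p = 0.66 with an estimated correlation, 0.0676 without Dim C and 0.0694 without Dim B and Bright C, the libraries that stood apart.

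Interferon and inflammatory genes were lower in Bright with a preset correlation, at an adjusted p = 0.291 and 0.108 with an estimated correlation. In the interferon list 17 of 31 genes fell and 1 rose (19 and 1 adjusted over the list alone; median -0.87, camera adjusted p = 3.8e-06), among them Ifi44 at -1.85 ± 0.24 and Stat2 at -1.33 ± 0.18. In the NF-kB list 16 of 25 fell and 3 rose (17 and 3 adjusted over the list alone; median -0.85, camera adjusted p = 0.0006), among them Traf1 at -2.21 ± 0.23 and Icam1 at -0.97 ± 0.14. Of 29 p53 target genes 11 fell and 2 rose (14 and 2 adjusted over the list alone; median -0.50, camera adjusted p = 0.038; adjusted p = 0.108 with an estimated correlation), Plk2 being the largest fall, whereas the mitotic spindle gene Psrc1 rose by 3.44 ± 0.44. This call was lost without Bright C (adjusted p = 0.0731) and without both Dim B and Bright C (0.0694). Immediate early genes, which respond within minutes to handling, fell in 8 of 26 cases with no rise (7 adjusted over the list alone; median -0.90, camera adjusted p = 0.0128), including Junb at -2.05 ± 0.31 and Nr4a1 at -1.57 ± 0.25. Their adjusted p was 0.729 with an estimated correlation, and the call was lost by fry (adjusted p = 0.0734) and without Dim B or Bright D (up to 0.0683).

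Genes of respiration and protein synthesis were higher in Bright with a preset correlation but did not pass with an estimated one. The oxidative phosphorylation, ribosomal protein and ribosome biogenesis lists had an adjusted p = 0.589, 0.777 and 0.108 with an estimated correlation. By fry, which does not compare a list with other genes, the first and last passed (adjusted p = 0.014 and 5.76e-06) and the ribosomal protein list did not (0.105). Of 73 oxidative phosphorylation genes 67 rose and none fell (71 adjusted over the list alone; median 1.02, camera adjusted p = 3.08e-12), with Cycs at 1.83 ± 0.25, Ndufa4 at 1.46 ± 0.24 and Cox5a at 1.47 ± 0.24. Of 75 cytosolic ribosomal protein genes 37 rose and none fell (54 adjusted over the list alone; median 0.76, camera adjusted p = 2.08e-05), with Rpl27 at 1.17 ± 0.26 and Rps16 at 1.28 ± 0.30. Ribosome biogenesis genes rose in 20 of 30 cases with no fall (20 adjusted over the list alone; median 0.54, camera adjusted p = 2.54e-05), with Fbl at 1.03 ± 0.16 and Odc1 at 0.90 ± 0.12. Of 27 genes of the integrated stress and unfolded protein responses 9 rose and 3 fell (median 0.37, camera adjusted p = 0.0421, lost without Bright B or Dim D at up to 0.107 and with genes of a mean count of at least 50 at 0.0571). The serine and folate pathway genes Psat1 (1.63 ± 0.14) and Mthfd2 (3.09 ± 0.29) rose and Trib3 fell by 3.33 ± 0.33. This list had an adjusted p = 0.546 with an estimated correlation. The library Bright C stood apart in the same measures. Ribosomal protein genes took 3.95% of its counts against 1.67 to 2.02% in the other Bright libraries, and its expression fell with gene length (slope -0.44), as did that of Dim B (slope -0.21). Without both libraries the medians were 0.80 for oxidative phosphorylation and 0.44 for ribosomal proteins. With each library's trend on gene length removed they were 0.61 (0.94 in the same fit without the removal) and 0.36 (from 0.65).

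The other 15 fixed lists did not pass in this comparison (camera adjusted p from 0.0667 to 0.987). Among them, 3 of 12 mitochondrially encoded genes rose and none fell. Numbers of genes that rose and fell were 4 and 5 of 18 for erythroid, 5 and 4 of 23 for lymphoid priming, 3 and 5 of 26 for granulocyte and monocyte priming, 2 and 1 of 9 for mast cells and basophils, and 8 and 7 of 29 for glycolysis and hypoxia. They were 2 and 1 of 25 for cholesterol synthesis and 7 and 9 of 26 for adhesion and niche genes. For cell types that a stem cell gate could let through they were 0 and 0 of 13 for neutrophils, 0 and 1 of 16 for monocytes and macrophages, 0 and 1 of 8 for B cells, 1 and 2 of 6 for T and NK cells, 2 and 5 of 14 for dendritic cells and MHC class II, and 0 and 3 of 14 for stroma and endothelium. None of 6 sex-linked genes changed. In the erythroid, lymphoid, T and NK, glycolysis and adhesion lists the median, the mean and the direction of the set test did not all have the same sign. Scaling by the upper quartile moved the median of all genes by about 0.1 (from -0.01 to -0.11), and no called list changed direction under that scaling or with DESeq2 size factors.

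**Figure D2:**
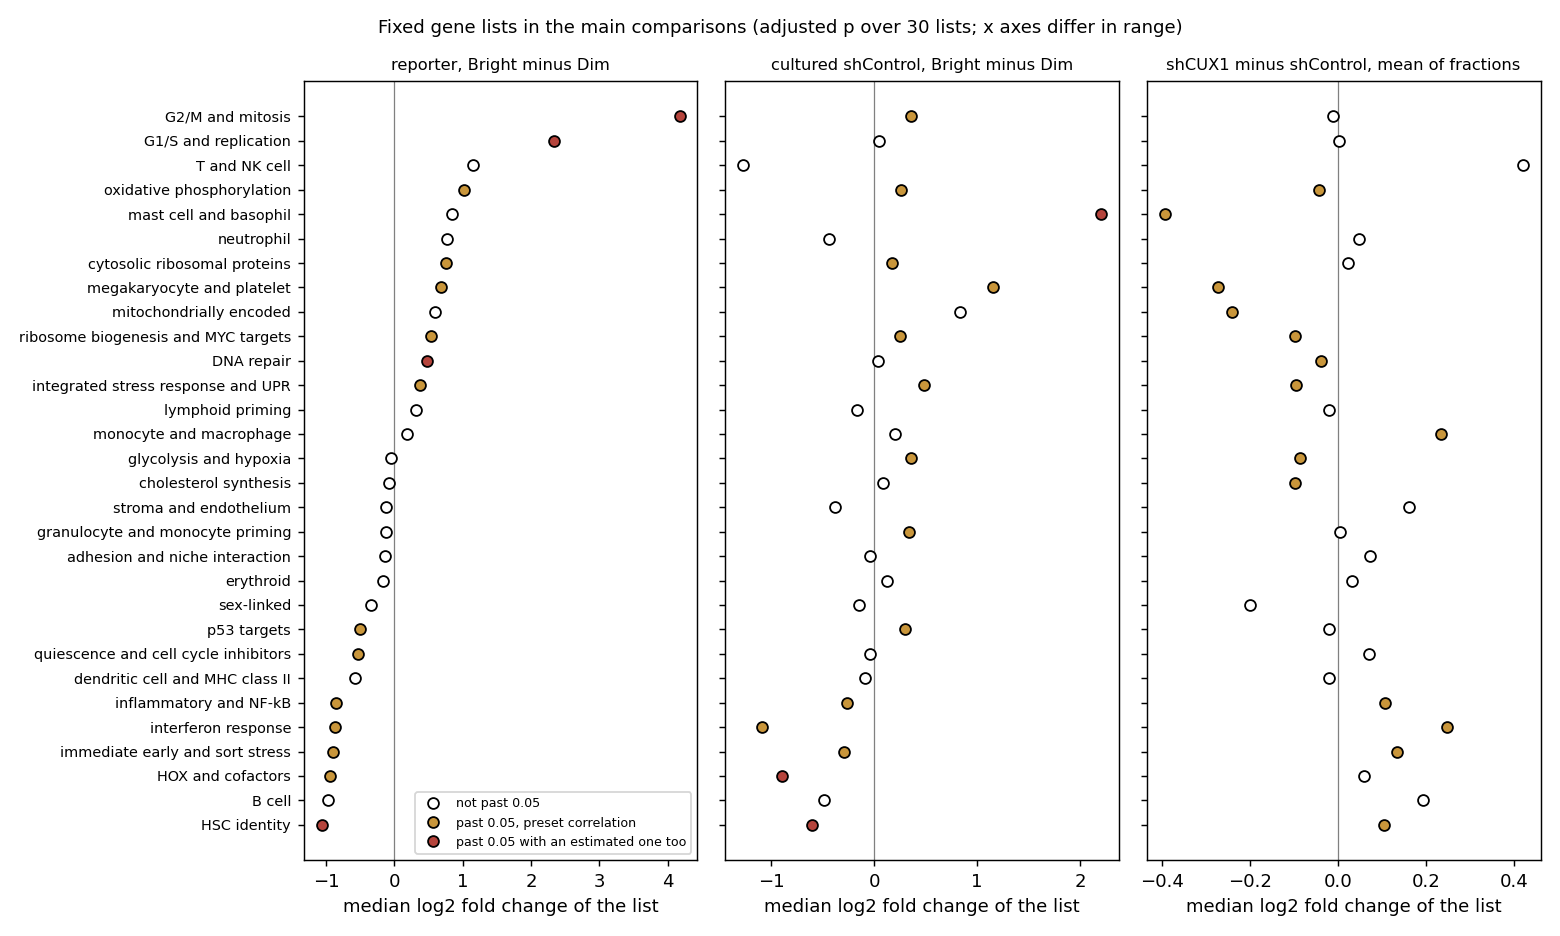
Median log2 fold change of each of the 30 fixed gene lists in 3 comparisons (reporter Bright over Dim, cultured shControl Bright over Dim, and shCUX1 over shControl averaged over fractions), with filled points for lists past a camera adjusted p of 0.05 with a preset correlation. The G2/M list reaches 4.18 in the reporter comparison and 0.35 in the cultured one.

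Int cells were compared with each of the other fractions. Between Dim and Int, 1189 of 13941 genes differed, 598 higher and 591 lower in Int (edgeR adjusted p under 0.05). Replication genes already rose in 29 of 32 cases (median 1.26) and G2/M genes in 25 of 28 (median 1.67), while 16 of 35 HSC identity genes fell (23 adjusted over the list alone; median -0.59). Cep55 (3.34 ± 0.50), the growth factor gene Fgf3 (3.23 ± 0.37), Neil3 (3.12 ± 0.37), Aunip (3.05 ± 0.51) and the centromere gene Cenpi (2.82 ± 0.33) rose furthest among genes that met the rule. Smtnl1 (-3.55 ± 0.36), Neo1 (-3.20 ± 0.47), Plk2 (-2.98 ± 0.30), the imprinted gene Dlk1 (-2.77 ± 0.28) and nestin, Nes (-2.74 ± 0.51), fell furthest among them. Of 30 lists 17 passed with a preset correlation and 5 with an estimated correlation: HSC identity, G1/S, G2/M, ribosome biogenesis and DNA repair (adjusted p from 0.00351 to 0.0374). The count was 709, 613, 715 and 742 without Int A, B, C and D in turn, and 2879 without Dim B and Bright C.

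Between Int and Bright, 1238 genes differed, 774 higher and 464 lower in Bright (62.5% higher; 49.6% with upper-quartile scaling). All 28 G2/M genes rose again (median 2.50), as did 26 of 32 replication genes (median 1.16), and 11 of 35 HSC identity genes fell (17 adjusted over the list alone; median -0.51). Ube2c (3.49 ± 0.58), Fam64a (3.31 ± 0.32), Kif18b (3.13 ± 0.55), Sapcd2 (3.11 ± 0.60) and Aurkb (3.10 ± 0.31) rose furthest among genes that met the rule. Sfrp1 (-2.69 ± 0.54), Smtnl1 (-2.67 ± 0.40), Plk2 (-2.47 ± 0.31) and Gbp9 (-2.36 ± 0.43) fell, as did the coagulation factor gene F13a1 (-2.94 ± 0.81, adjusted p = 0.0386), whose call was lost in 7 of the 8 fits that left out 1 library (adjusted p up to 0.13). Of 30 lists 10 passed with a preset correlation and 4 with an estimated correlation: HSC identity, G1/S, G2/M and DNA repair (adjusted p from 0.00844 to 0.021). Mature neutrophil genes averaged 9.54 ± 5.75 CPM in Int against 1.08 ± 0.65 in Dim and 1.71 ± 1.77 in Bright. They were at 14.8, 12.1 and 9.72 CPM in Int A, B and D and 1.51 CPM in Int C. This list was higher in Int than in either other fraction, with 0 of 13 genes past the test against Dim and 2 against Bright (camera adjusted p = 0.00477 and 0.00865; adjusted p = 0.412 and 0.516 with an estimated correlation). The 2 genes, Camp and Chil3, were each lost in 6 of the 8 fits that left out 1 library (adjusted p up to 0.156 and 0.0863), without Dim B and Bright C (0.135 and 0.0769) and with no filter on low counts (0.102 and 0.0521). Camp also lost its call with limma voom (0.336), with the replicate letter as a block (0.0543) and against a fold of 1.2 (0.0543). The count of changed genes was 788, 742, 631 and 572 without Int A, B, C and D, 693 without Bright A and 2183 without Dim B and Bright C.

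After 3 days of culture with the control hairpin, Bright and Dim cells still differed widely. Bright cells had more RNA of mast cell genes and less of HSC identity and HOX genes. With a preset correlation megakaryocyte and granulocyte genes were also higher and interferon genes lower, at an adjusted p = 0.284, 0.304 and 0.0686 with an estimated correlation. The granulocyte list also lost its preset call without Bright shControl D and Dim shCUX1 B (adjusted p = 0.0531). Mki67 was 351 ± 39.6 CPM in Bright shControl (n = 4) and 271 ± 31.9 in Dim shControl (n = 3), and Procr was 29.2 ± 18.2 and 110 ± 11.1 CPM. Of 14548 genes tested, 3127 differed, 1224 higher and 1903 lower in Bright (edgeR adjusted p under 0.05; 39.1% higher, and 29.3% with upper-quartile scaling). Among genes that met the rule, those that rose furthest were Ltbp1 (chromosome 17, 75005529 to 75392967) at 4.92 ± 1.18, the platelet chemokine gene Ppbp at 4.84 ± 0.82, thrombospondin Thbs1 at 4.77 ± 1.16, granzyme Gzmb at 4.70 ± 1.03 and Dhrs3 at 4.42 ± 0.50. Mrvi1 (3.87 ± 0.91), Scin (3.51 ± 0.45), Cst7 (3.46 ± 0.36), platelet factor Pf4 (3.43 ± 0.62) and the platelet glycoprotein gene Gp1bb (3.35 ± 0.85) followed. Among genes that met it, those that fell furthest were Igf2bp2 (chromosome 16, 22059009 to 22163299) at -4.42 ± 0.41, the MHC class II invariant chain Cd74 at -3.82 ± 0.32, Tspan7 at -3.68 ± 0.26, Clip3 at -3.55 ± 0.29 and Gimap4 at -3.17 ± 0.34. Ncam2 (-3.11 ± 0.46), Lsr (-3.07 ± 0.24), muscle glycogen phosphorylase Pygm (-3.00 ± 0.28), the interferon-inducible GTPase Iigp1 (-2.90 ± 0.31) and Tns2 (-2.90 ± 0.26) followed.

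Of 27 megakaryocyte and platelet genes in these cultured cells 18 rose and 1 fell (19 and 1 adjusted over the list alone; median 1.16, camera adjusted p = 2.85e-10), with Gata1 at 2.37 ± 0.34, Gp5 at 2.63 ± 0.41 and Itgb3 at 2.46 ± 0.40. Of 11 mast cell and basophil genes 6 rose and none fell (7 and 1 adjusted over the list alone; median 2.20, camera adjusted p = 0.000137), with carboxypeptidase Cpa3 at 1.85 ± 0.24 and the interleukin-33 receptor gene Il1rl1 at 3.32 ± 0.44. Granulocyte and monocyte priming genes rose in 9 of 24 cases and fell in 2 (10 and 2 adjusted over the list alone; median 0.34, camera adjusted p = 0.00342), with Nkg7 at 2.18 ± 0.18 and Ms4a3 at 2.41 ± 0.30. HSC identity genes fell in 21 of 35 cases and 1 rose (23 and 1 adjusted over the list alone; median -0.61, camera adjusted p = 8.15e-13), with Mllt3 at -1.58 ± 0.13 and Ndn at -2.65 ± 0.25. HOX genes fell in 12 of 22 cases and 1 rose (14 and 1 adjusted over the list alone; median -0.90, camera adjusted p = 1.95e-07), with Hoxa10 at -1.59 ± 0.16 and Hoxb6 at -3.85 ± 0.49. Interferon genes fell in 24 of 31 cases and 1 rose (28 and 1 adjusted over the list alone; median -1.09, camera adjusted p = 3.66e-15), with Gbp3 at -1.76 ± 0.22 and Ifi44 at -2.57 ± 0.34. With an estimated correlation the HSC identity, HOX and mast cell lists passed (adjusted p = 0.0195, 0.0206 and 0.0206).

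Mitotic genes were also higher in cultured Bright cells, by less than in the reporter experiment, though the difference between the experiments was not tested. G2/M genes rose in 16 of 28 cases with no fall (21 adjusted over the list alone; median 0.35, camera adjusted p = 4.35e-08; adjusted p = 0.296 with an estimated correlation), including Aurkb at 0.41 ± 0.08, whereas none of 32 replication genes rose and 1, the cyclin gene Ccnd1 (-1.59 ± 0.19), fell (camera adjusted p = 0.411). Genes that rose, with none falling, numbered 10 of 30 for ribosome biogenesis (17 adjusted over the list alone), 6 of 73 for oxidative phosphorylation (0 adjusted over the list alone), 0 of 75 for ribosomal proteins and 10 of 29 for glycolysis and hypoxia (11 adjusted over the list alone), the last with the glucose transporter gene Slc2a3 at 0.89 ± 0.14. In the stress response list 16 of 27 rose and 1 fell (18 and 1 adjusted over the list alone), with Vldlr at 2.30 ± 0.34 and Xbp1 at -0.91 ± 0.11. All 5 of these lists passed with a preset correlation (camera adjusted p from 7.48e-07 to 0.000303), and with an estimated correlation they had an adjusted p from 0.144 to 0.698. By fry the oxidative phosphorylation and ribosomal protein lists did not pass (adjusted p = 0.113 and 0.286). In the NF-kB list 10 of 25 fell and 2 rose (camera adjusted p = 0.0109; adjusted p = 0.304 with an estimated correlation). Among immediate early genes 7 of 25 fell and 1 rose, with Dusp1 at -0.96 ± 0.14. This list had a camera adjusted p = 0.0353 (0.334 with an estimated correlation) and lost its call without Bright shControl A or Dim shControl D (up to 0.17). Among p53 targets 6 of 29 rose and 2 fell (camera adjusted p = 0.017; adjusted p = 0.58 with an estimated correlation), a call that was lost without Dim shControl C or Bright shControl D (up to 0.351), by fry (0.104) and without Bright shControl D and Dim shCUX1 B (median 0.067, adjusted p = 0.354). The count of changed genes was 2004 without Dim shControl D. Gzmb lost its call in a fit of the compared groups alone (0.0846).

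Knockdown of CUX1 changed far fewer genes than separated the fractions, and by smaller amounts. Averaged over the 3 fractions, 192 of 14548 genes differed between shCUX1 and shControl, 110 higher and 82 lower (edgeR adjusted p under 0.05), 29 of them by more than 2-fold. With the replicate letter as a block 433 genes passed, 190 of them among the 192. Among genes that met the rule, which here asked for the same sign in all 3 fractions, those that rose furthest were Ptprn, a receptor-type phosphatase of secretory granules (chromosome 1, 75247041 to 75264208), at 1.21 ± 0.18 log2 units (adjusted p = 0.000899), and the transcriptional repressor Bcl6b (chromosome 11, 70224127 to 70229798) at 1.08 ± 0.14 (adjusted p = 0.000163). Next were Rasip1 at 1.06 ± 0.15, Cd74 at 1.00 ± 0.17 and Gdpd3 at 0.98 ± 0.15. Clip3 (0.95 ± 0.15), Ms4a6d (0.91 ± 0.19), Rap1gap (0.78 ± 0.17), Ms4a6b (0.78 ± 0.18) and Cd200r4 (0.77 ± 0.17) followed. Bcl6b was higher with shCUX1 in each fraction, at 15.1 ± 2.45 against 9.73 ± 0.828 CPM in Dim, 7.02 ± 2.41 against 2.61 ± 0.743 in Int and 3.54 ± 0.793 against 1.56 ± 0.268 in Bright. It was also lower in Bright than in Dim cells of the reporter experiment (3.75 ± 1.16 and 7.73 ± 2.78 CPM). After Cux1, the genes under the same rule that fell furthest were osteopontin, Spp1 (chromosome 5, 104435111 to 104441053), at -1.22 ± 0.18, P-selectin, Selp (chromosome 1, 164115264 to 164150026), at -1.18 ± 0.20, and the kinase gene Hipk2 at -0.98 ± 0.24. Next were the RNA-binding protein gene Hnrnpa0 at -0.96 ± 0.19 and Cap1, which acts on actin, at -0.87 ± 0.15. Ttc39a (-0.78 ± 0.16), securin, Pttg1 (-0.76 ± 0.13), the G protein alpha subunit gene Gnaq (chromosome 19, 16132831 to 16387453) at -0.76 ± 0.09 (adjusted p = 9.9e-05) and Rasd1 (-0.75 ± 0.19) followed. Spp1 went from 6.78 ± 0.894 to 3.33 ± 0.873 CPM in Dim, from 8.68 ± 2.08 to 3.82 ± 0.689 in Int and from 9.98 ± 4.41 to 3.65 ± 0.969 in Bright.

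Some of these calls rested on single libraries. Against a fold of 1.2 in place of no change, 27 genes passed, and Hipk2, Hnrnpa0, Ttc39a, Rasd1, Ms4a6d, Rap1gap, Ms4a6b and Cd200r4 did not (adjusted p from 0.0861 to 0.321). The calls of Hipk2 and Rasd1 were each lost in 16 of the 23 fits that left out 1 library (adjusted p up to 0.147 and 0.124) and that of Ms4a6b in 7 of 23 (up to 0.0798). The call of Rap1gap was lost without Dim shControl A or C (up to 0.0735), and those of Cd200r4 and Ms4a6d without Dim shControl C (0.0758 and 0.0604). The 192 genes became 101 without Dim shControl C, 126 without Bright shCUX1 A and 478 without Bright shControl D. Leaving out Bright shControl D and Dim shCUX1 B together gave 822 genes, of which 191 were among the 192. The 3' UTRs of Selp, Hnrnpa0, Gnaq and Rasd1 hold the 7 bases AAACAAA, as does that of Cux1, whereas those of Spp1, Hipk2, Cap1, Ttc39a and Pttg1 do not. Among the 10 higher genes named above, that of Ms4a6b holds it. This heptamer occurred in 47 of the 73 lower genes with an annotated 3' UTR, where 24.8 were expected from genes of like 3' UTR length. With A content held too, 27.8 were expected. It was picked as the most enriched of 16322 heptamers searched in these same genes, so some excess follows from the search itself.

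Few members of any fixed list passed on their own after knockdown, and no list passed with an estimated correlation. With the preset correlation 14 of 30 lists passed (7 by fry), and the smallest adjusted p with an estimated correlation was 0.109. Interferon genes were higher (0 of 31 rose; 3 adjusted over the list alone; median 0.25, camera adjusted p = 3.52e-09; adjusted p = 0.257 with an estimated correlation), with Ifit1 at 0.71 ± 0.21 and Rtp4 at 0.47 ± 0.14. HSC identity genes were higher (0 of 35 rose; median 0.11, camera adjusted p = 0.000541; adjusted p = 0.257 with an estimated correlation), with Mllt3 at 0.22 ± 0.07 and Apoe at 0.55 ± 0.17. NF-kB genes (0 of 25 rose; 6 adjusted over the list alone; median 0.11, camera adjusted p = 0.00368) included Relb at 0.48 ± 0.14. Immediate early genes (2 of 25 rose; 3 adjusted over the list alone; median 0.13, camera adjusted p = 0.000817) included Dusp1 at 0.40 ± 0.08 and Egr1 at 0.50 ± 0.10, both past the test. Monocyte and macrophage genes (1 of 11 rose; median 0.24, camera adjusted p = 0.00848) included the endotoxin co-receptor gene Cd14 at 0.98 ± 0.24, a call lost in 12 of 23 fits that left out 1 library (adjusted p up to 0.103). The last 3 lists had an adjusted p = 0.278, 0.257 and 0.257 with an estimated correlation, and the NF-kB list did not pass by fry (0.0642).

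Lists that were lower after knockdown included megakaryocyte and platelet genes, of which 1 of 27 fell (3 adjusted over the list alone; median -0.27, camera adjusted p = 3.84e-05; adjusted p = 0.46 with an estimated correlation), with Selp past the test and Gata1 at -0.57 ± 0.17. Mast cell and basophil genes (1 of 11 fell; 2 adjusted over the list alone; median -0.39, camera adjusted p = 0.00248; adjusted p = 0.109 with an estimated correlation) included Il1rl1 at -0.98 ± 0.22, a call lost in 6 of 23 fits that left out 1 library (up to 0.109), whose 3' UTR holds AAACAAA. Ribosome biogenesis genes (0 of 30 fell; median -0.10, camera adjusted p = 2.06e-05) and stress response genes (0 of 27 fell; 2 adjusted over the list alone; median -0.09, camera adjusted p = 0.00214) were lower, at an adjusted p = 0.278 and 0.279 with an estimated correlation. In the DNA repair list 2 of 35 fell (3 adjusted over the list alone; median -0.04, camera adjusted p = 0.0217), the checkpoint kinase gene Chek2 at -0.42 ± 0.06 and the mismatch repair gene Mlh1 at -0.43 ± 0.07. Its adjusted p was 0.272 with an estimated correlation and up to 0.0706 without Dim shControl C or Int shControl D. The 3' UTR of Chek2 holds AAACAAA and that of Mlh1 does not. Glycolysis (median -0.09), cholesterol synthesis (-0.10), oxidative phosphorylation (-0.04) and mitochondrially encoded genes (-0.24) had camera adjusted p from 0.00394 to 0.043 with 0 genes past the test, and an adjusted p from 0.529 to 0.952 with an estimated correlation. By fry the megakaryocyte and stress response lists had an adjusted p = 0.204 and 0.0677, and these 4 lists from 0.255 to 0.754. The first was lost without Bright shControl D (0.099) and without it and Dim shCUX1 B (0.103), the second without Bright shControl C (0.0702), the third in 7 of 23 such fits (up to 0.729) and the last in 12 of 23 (up to 0.422) and with genes of a mean count of at least 50 (0.054).

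G1/S and replication genes (median 0.00) and G2/M genes (median -0.01) did not pass (camera adjusted p = 0.826 for both lists). Outside the called lists, the granulocyte protease gene Ctsg fell by 2.72 ± 0.58, and Cd79b (0.37 ± 0.07), Txnip (0.36 ± 0.09), Hoxa10 (0.36 ± 0.09) and the junction adhesion gene Jam3 (0.56 ± 0.10) rose.

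**Figure D3:**
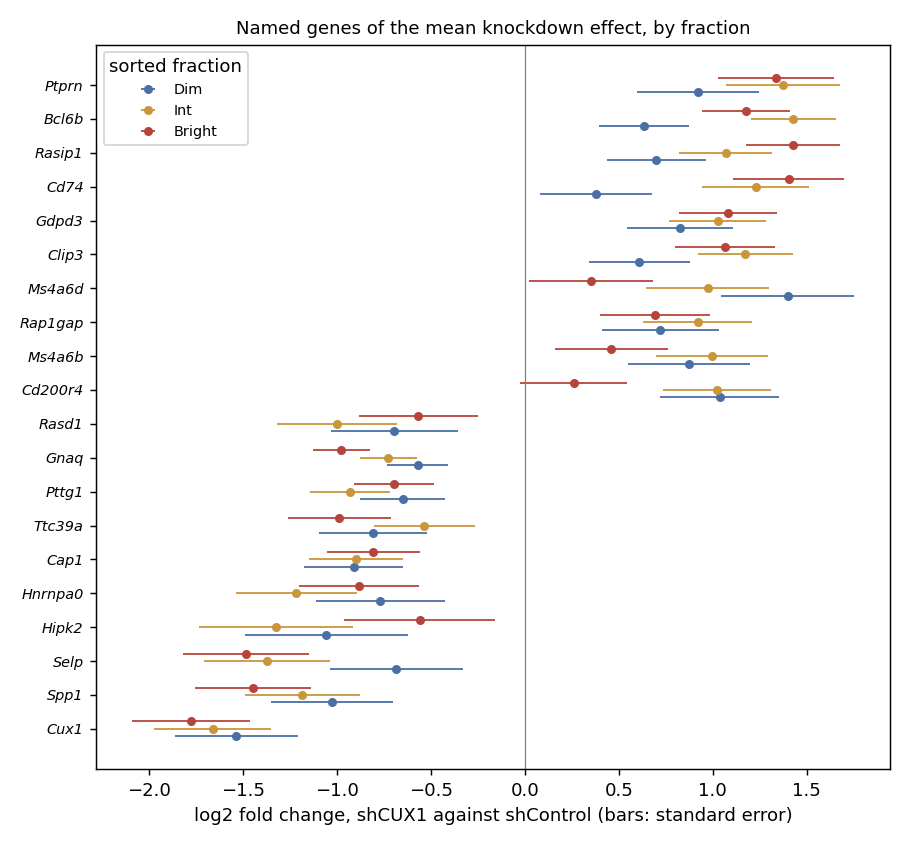
Log2 fold change of shCUX1 against shControl in Dim, Int and Bright for the named genes of the mean knockdown effect, with bars for the standard error. In every fraction the value of Bcl6b is positive, and those of Spp1 and Gnaq are negative.

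Within single fractions edgeR called few genes. In Dim, edgeR called 0 of 14548 genes, with 550 at an unadjusted p under 0.05, while DESeq2 called 5 and limma voom 3. In Int 4 genes rose and none fell (1077 at an unadjusted p under 0.05), while DESeq2 called 55, limma voom 63 and a fit with the replicate letter as a block 11. The 4 were the collagen chaperone gene Serpinh1 at 1.82 ± 0.30, Bcl6b at 1.43 ± 0.23, Lyrm7 at 1.42 ± 0.19 and the secreted glycoprotein gene Fstl1 at 0.96 ± 0.17. Lyrm7 passed in all 8 fits that left out 1 library, whereas Bcl6b and Fstl1 were lost in 5 of 8 and Serpinh1 in 6 of 8 (adjusted p up to 0.157). A fit of the Int groups alone called 0 genes (983 at an unadjusted p under 0.05). Without Int shControl A, B or C or Int shCUX1 A the count was 1 in each case, without Int shCUX1 C it was 2, and without Int shControl D or Int shCUX1 D it was 7 and 9.

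In Bright 11 genes passed, 6 higher and 5 lower (953 at an unadjusted p under 0.05; 18 with the replicate letter as a block, 61 with DESeq2 and 95 with limma voom). Besides Cux1, they included Rasip1 at 1.43 ± 0.25, the immediate early gene Egr1 at 0.98 ± 0.17 and the calpain gene Capn2 at 0.71 ± 0.12 among the higher genes. The lower ones were Gnaq at -0.98 ± 0.15, from 14.7 ± 1.77 to 7.47 ± 1.21 CPM, the glucosylceramide synthase gene Ugcg at -0.83 ± 0.13, Ankrd49 at -0.59 ± 0.11 and Chek2 at -0.52 ± 0.10. The 3' UTRs of the 4 lower genes hold AAACAAA, as does that of the higher gene Egr1 and as do those of 3778 of the 12892 tested genes with an annotated 3' UTR. Each of these calls was lost in 4 to 7 of the 8 fits that left out 1 library (adjusted p up to 0.151) and in a fit of the Bright groups alone, which called 0 genes (723 at an unadjusted p under 0.05). The count was 5, 1, 0 and 24 without Bright shControl A, B, C and D, and 0, 1 and 0 without Bright shCUX1 A, B and C.

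The difference of the knockdown effect between Bright and Dim was tested directly, and edgeR called 0 of 14548 genes (364 at an unadjusted p under 0.05; 0 with DESeq2 and with limma voom). Effects seen in a single fraction are thus not shown to differ between these fractions. Of 30 lists 7 passed with a preset correlation in this test and none with an estimated correlation (smallest adjusted p = 0.253) or by fry. In Dim 13 lists passed with a preset correlation and 2, mast cell and DNA repair, with an estimated correlation (adjusted p = 0.0367 and 0.0482). In Int 11 and in Bright 4 passed with a preset correlation and none with an estimated correlation.

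The genes that differed between reporter Bright and Dim were then followed as a signature, 2701 higher and 2496 lower genes that were also measured in the knockdown experiment, with no library in common. In cultured shControl cells the higher genes of this signature lay 0.71 log2 units above its lower genes in the comparison of Bright with Dim (fry adjusted p = 4.34e-05 over 6 comparisons). Of the called genes, 573 genes were higher in both experiments (229 expected by chance) and 1084 lower in both (337 expected). Across 13684 genes, which are not independent replicates, the log2 fold changes of the 2 experiments had r = 0.527 and rho = 0.530. The signature score, the mean log2 CPM of its higher genes minus that of its lower genes, was 3.09 ± 0.161 in Bright shControl (n = 4) and 2.01 ± 0.0219 in Dim shControl (n = 3), a difference of 1.08 (two-sided exact permutation p = 0.0286, Benjamini-Hochberg adjusted 0.0572 over 4 comparisons).

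After knockdown the signature lay on the other side of 0 without passing the test. The median of its higher genes minus that of its lower genes was -0.12 (fry adjusted p = 0.201), with 1860 of 2701 higher genes below 0 and 1754 of 2496 lower genes above 0. By fraction the difference was -0.07 in Dim, -0.19 in Int and -0.09 in Bright (fry adjusted p = 0.632, 0.201 and 0.521), and the change of it from Dim to Bright was -0.03 (fry adjusted p = 0.842). At an unadjusted p of 0.05, which the value with all libraries did not reach, it passed without Dim shCUX1 B (-0.16), Int shCUX1 B (-0.14), Int shControl D (-0.14) or Bright shControl D (-0.15), and without the first and last of these together (-0.17). It also passed that threshold with the 100 genes of smallest p in each direction (-0.25) and with the replicate letter as a block (-0.13). Scores were 2.91 ± 0.0763 in Bright shCUX1 against 3.09 ± 0.161 in Bright shControl (n = 4 and 4, difference -0.18, exact permutation p = 0.0286, adjusted 0.0572). In Bright, where the letters pair the libraries, the score was lower with shCUX1 in all 4 pairs (differences of -0.18, -0.11, -0.39 and -0.036 for A to D; exact sign-flip p = 0.125, the smallest that 4 pairs allow). The unpaired test was lost without any 1 of the 4 Bright shCUX1 libraries or Bright shControl C (exact permutation p from 0.0571 to 0.143), and without the last the difference was -0.10. They were 2.61 ± 0.253 against 2.85 ± 0.171 in Int (difference -0.23, n = 4 and 4, exact permutation p = 0.171, adjusted 0.228) and 1.93 ± 0.213 against 2.01 ± 0.0219 in Dim (difference -0.08, n = 4 and 3, exact permutation p = 0.6). Without Dim shCUX1 B the difference in Dim was -0.19 (exact permutation p = 0.1, the smallest possible for 3 against 3).

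Called genes of knockdown and of the reporter comparison were also counted together. Of the 105 genes higher after knockdown and measured in both experiments, 51 were lower in reporter Bright than Dim, where 19.2 were expected by chance (Fisher's exact test, p = 1.19e-12), and 6 were higher, where 20.7 were expected (p = 6.59e-05). Of the 80 genes lower after knockdown, 18 were higher in reporter Bright, where 15.8 were expected (Fisher's exact test, p = 0.572), and 4 were lower, where 14.6 were expected (p = 0.000753). The log2 fold changes of knockdown and of reporter Bright over Dim had r = -0.236 and rho = -0.265 across the 13684 genes. Genes are not independent replicates, so these Fisher p-values and correlations do not measure the spread between libraries. The signature test, which uses that spread, did not pass after knockdown (fry adjusted p = 0.201).

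**Figure D4:**
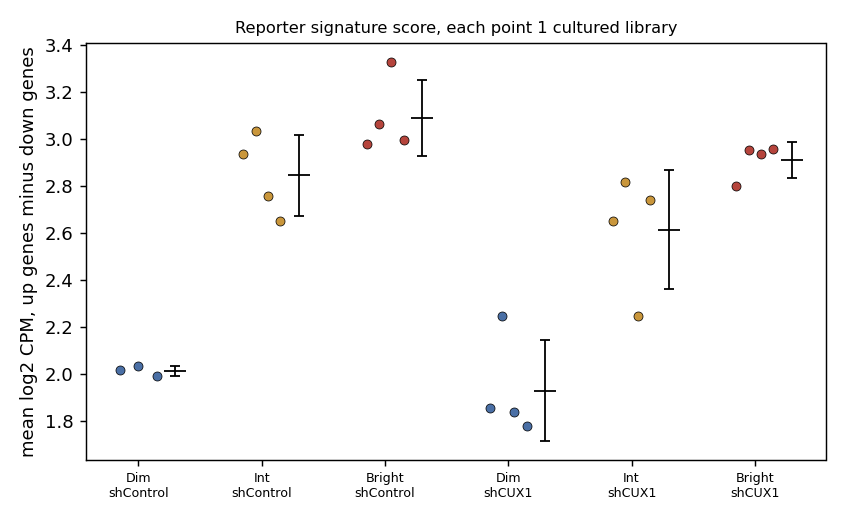
Signature score of each knockdown library (mean log2 CPM of the 2701 genes higher in reporter Bright minus that of the 2496 lower genes), with points for libraries and bars for the mean and SD of the 6 groups. Group means rise from 2.01 in Dim shControl to 3.09 in Bright shControl, and are 1.93, 2.61 and 2.91 with shCUX1 in Dim, Int and Bright.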

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

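The gene length and library tests in this part were chosen after the data were seen, whereas the search for far libraries and the test of the difference between fractions were planned. Among 109 groups of 4 libraries examined over library measures and printed gene levels, 12 had a library whose distance to the nearest other was large against the range of the group, where chance gives about 1 in 20 groups.

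Ribosomal protein and oxidative phosphorylation genes were higher in reporter Bright than Dim (medians 0.76 and 1.02), and Bright C lay far from the other Bright libraries in its share of ribosomal protein counts (3.95% against 1.67 to 2.02%) and of mitochondrial counts (0.243% against 0.142 to 0.152%). Without Bright C and Dim B the oxidative phosphorylation median was 0.80, so these libraries do not account for that difference, while the ribosomal protein median was 0.44, and how much of its size came from them stays open. With each library's trend on gene length removed, the medians were 0.61 (0.94 in the same fit without the removal) and 0.36 (from 0.65), both still past the preset threshold (adjusted p = 5.67e-15 and 0.000109), so the trend is not the whole of either difference, but its part in their size cannot be told apart. With an estimated correlation neither list passed (adjusted p = 0.589 and 0.777). A difference in biology between the fractions was not tested apart from these explanations and stays open.

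Other far libraries were a total of 56.9 M counts in Bright shCUX1 C (others 51.3 to 51.9 M), and a ribosomal protein share of 3.46% (others 2.38 to 2.50%) and a length slope of -0.18 (others 0.04 to 0.08) in Int shControl A. The signature score was 2.25 in Dim shCUX1 B (others 1.78 to 1.86) and 2.80 in Bright shCUX1 A (others 2.94 to 2.96). In CPM, Procr was 114 in Dim shCUX1 A (others 142.5 to 146.9), Bcl6b was 1.74 in reporter Int C (others 3.85 to 4.04) and Spp1 was 3.42 in Bright shControl D (others 11.4 to 12.8). Gnaq was 11.3 in Dim shCUX1 D (others 8.54 to 8.99) and 9.28 in Bright shCUX1 B (others 6.70 to 7.04).

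For 7 gene lists the knockdown effect differed between Bright and Dim with a preset correlation. The median difference was 0.13 for G1/S and replication (-0.05 in Dim, 0.07 in Bright; camera adjusted p = 8.61e-05), 0.16 for ribosome biogenesis (-0.12 and 0.04; 0.000152), 0.20 for cholesterol synthesis (-0.17 and 0.03; 0.000114) and 0.14 for DNA repair (-0.10 and 0.03; 0.000965). It was -0.53 for mitochondrially encoded genes (0.10 and -0.58; 0.000188), -0.078 for oxidative phosphorylation (-0.0015 and -0.092; 0.000965) and -0.12 for interferon response (0.25 and 0.10; 0.0174). No list passed with an estimated correlation (smallest adjusted p = 0.253) or by fry. Without Dim shCUX1 B and Bright shControl D 5 of the 7 still passed in the same direction; cholesterol synthesis and interferon response did not (adjusted p = 0.662 and 0.354). Among fits that left out 1 library, the mitochondrial list was lost without Bright shControl C (0.222), oxidative phosphorylation without Dim shCUX1 B, Dim shControl C or Bright shControl C (up to 0.448). Cholesterol synthesis was lost without Bright shControl D (0.512) and interferon response in 5 of 15 fits (up to 0.264), and 11 lists passed without Bright shCUX1 A.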

How the results depend on the processing

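Values without the libraries that stood apart (Dim B and Bright C; Dim shCUX1 B and Bright shControl D), with the length trend removed and within letter pairs of the score come from tests chosen after the data were seen; the other alternatives were planned. There were 10303 alternative values of 511 results for named genes, each result being a gene in a comparison. Of these values 9786 stayed on the same side of the threshold in the same direction, 366 were lost, 151 passed only in the alternative and 0 reversed. Results that were not called to begin with, which could not be lost, count among those that stayed. Of 2300 values of 120 list medians, 2124 stayed, 116 were lost, 58 were gained and 2 reversed. Both were for p53 targets in the difference of the knockdown effect (median 0.02, mean -0.07, not called): 0.17 without the libraries that stood apart and 0.15 without Bright shControl D (from -0.046 to 0.15 over fits without 1 library). The count for reporter Bright against Dim stayed within 1.5 times of 5254 in every setting (3998 to 6355), and that for the difference between fractions was 0 throughout. The cause of the other changes was not tested, except that a test against a fold of 1.2 asks more of the data.

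DESeq2 and limma voom called 1955 and 3329 genes for Int against Dim (1189 with edgeR), 2149 and 2502 for Bright against Int (1238), and 491 and 1089 for the mean knockdown effect (192). They called 5 and 3 for knockdown in Dim (0), 55 and 63 in Int (4), 61 and 95 in Bright (11); voom called 5487 for cultured Bright against Dim (3127). Against a fold of 1.2 the counts were 705, 656, 27, 0 and 1768 for Int against Dim, Bright against Int, mean knockdown, knockdown in Bright and cultured Bright against Dim. Fits of the compared groups alone (edgeR) called 0 genes for knockdown in Int and in Bright (983 and 723 at an unadjusted p under 0.05). Without the libraries that stood apart the counts were 2879, 2183, 822, 19 and 36 for Int against Dim, Bright against Int, mean knockdown, knockdown in Int and in Bright.

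Lists past the threshold fell from 15 to 4 (reporter Bright against Dim), from 15 to 3 (cultured), from 14 to 0 (mean knockdown) and from 7 to 0 (difference between fractions) with an estimated correlation, and from 14 to 7 and from 7 to 0 by fry. At an unadjusted fry p of 0.05 the signature under knockdown passed with 100 genes in each direction (-0.25), without the libraries that stood apart (-0.17) and with the length trend removed (-0.13), and the score difference in Bright with 100 genes was -0.28 (exact permutation p = 0.114).

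With the replicate letter as a block, counts were 433 for the mean knockdown effect (190 of the 192 shared), 11 and 18 for knockdown in Int and Bright, 5007, 1139 and 1057 for reporter Bright against Dim, Int against Dim and Bright against Int. With this block they were 0 for knockdown in Dim and for the difference between fractions, and 3174 for cultured Bright against Dim, and the signature under knockdown was -0.13, past an unadjusted fry p of 0.05. Of the pairs of groups in which each library correlated best with its own letter, only Bright shControl with Bright shCUX1 (8 of 8) and Dim shControl with Bright shControl (6 of 6) also had every correlation over 0.1. In Dim and Int, where the letters did not reach this, the score was lower with shCUX1 in 3 of 3 and 3 of 4 letter pairs (mean -0.19 and -0.23, exact sign-flip p = 0.25 for both). That p is the smallest that 3 pairs allow in Dim, whereas 0.125 was possible in Int.

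Leaving out 1 library gave 4420 to 5659 genes for reporter Bright against Dim, 613 to 1201 for Int against Dim, 572 to 1850 for Bright against Int. It gave 101 to 478 for the mean knockdown effect, 0 to 2 in Dim (2 without Dim shCUX1 D), 1 to 9 in Int, 0 to 24 in Bright, 0 to 0 for the difference and 2004 to 3995 for cultured Bright against Dim. Lists called were 13 to 16, 11 to 15 (mean knockdown), 14 to 16 (cultured) and 6 to 11 (difference). The signature ranged from 0.61 to 0.83 in cultured cells and from -0.16 to -0.086 under knockdown, and score differences from -0.22 to -0.10 in Bright, -0.30 to -0.11 in Int, -0.19 to -0.03 in Dim and 1.00 to 1.11 for Bright against Dim. In Bright that test was lost without Bright shCUX1 A, B, C or D or Bright shControl C (exact permutation p from 0.0571 to 0.143). The Cux1 difference ranged from 0.24 to 1.01 (reporter Bright against Dim), 0.17 to 0.91 (Int against Dim), -0.19 to 0.36 (Bright against Int), and -1.84 to -1.65 (mean knockdown). It ranged over -1.999 to -1.31, -1.95 to -1.51 and -2.07 to -1.72 (Dim, Int, Bright) and 0.11 to 0.37 (cultured). Of 295 calls of named genes 52, and of 51 list calls 16, were lost without 1 library or more. No library was shallow enough to be left out for its depth, so that alternative gave no value, nor did the compared groups alone for the mean knockdown effect, which uses all groups. At these depths reporter Bright against Dim recovered 7.46% of simulated 1.5-fold changes, with 200 genes changed. The real comparison called 5254 genes, 2493 of them by more than 2-fold, so changes under 2-fold were called there too. The cut-off of an adjusted p depends on how many genes differ. The simulated share therefore cannot tell how many small changes were missed in the real comparison.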

Other observations

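The heptamer search, its 3 follow-up tests and the gene length, library and letter pair tests on the signature were chosen after the knockdown results were seen, whereas the signature without cell cycle, ribosomal protein and immediate early genes and the counts over other splits of the libraries were planned.

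By fraction, gene lists moved after knockdown as follows, with a preset correlation between genes. In Dim, mast cell and basophil genes were lower (median -0.51, camera adjusted p = 0.000252; adjusted p = 0.0367 with an estimated correlation) and DNA repair genes were lower (median -0.10, 8.42e-05; 0.0482 with an estimated correlation), while interferon genes were higher (median 0.25, 2.75e-07; 0.29 with an estimated correlation). In Int, interferon genes were higher (median 0.39, camera adjusted p = 4.61e-11), megakaryocyte and platelet genes were lower (-0.38, 3.11e-05) and ribosome biogenesis genes were lower (-0.17, 2.01e-08). With an estimated correlation these had an adjusted p = 0.29, 0.486 and 0.29. In Bright, immediate early genes were higher (0.15, camera adjusted p = 0.00137) and mitochondrially encoded genes lower (-0.58, 0.00116), at an adjusted p = 0.732 and 0.764 with an estimated correlation. In the fraction named, 0 members of these lists passed over all genes, except Egr1 in Bright.

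The shift of the reporter signature after knockdown, opposite to its direction in Bright cells (-0.12, fry adjusted p = 0.201), did not pass its test, so a move towards the Dim profile is not shown. Without cell cycle, ribosomal protein and immediate early genes the difference was -0.12 again, which decides nothing, as 2606 of 2701 higher and 2488 of 2496 lower genes were left. It was not a trend with gene length, whose removal gave -0.13 (from -0.12 in the same fit). Without Dim shCUX1 B and Bright shControl D the difference was -0.17, but these libraries were picked after the data were seen. Dim shCUX1 B had a score of 2.25 against 1.78 to 1.86 in the others of its group. Leaving it out thus makes the shift larger by itself, and this fit decides nothing. Of called genes higher after knockdown 51 were lower in reporter Bright (19.2 expected), and of those lower after knockdown 4 were lower (14.6 expected) and 18 higher (15.8 expected). What stays open is whether CUX1 itself or the hairpin acts on these genes, since a single contrast of shCUX1 with shControl may hold both, and, at an adjusted p of 0.0572 for the score in Bright and lower scores in all 4 of its letter pairs (exact sign-flip p = 0.125, the smallest possible), but a difference of -0.10 without Bright shControl C (exact permutation p = 0.0571), whether the shift is there at all.

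Genes lower after knockdown in all 3 fractions (80 without Cux1, 73 with an annotated 3' UTR) were searched for a shared heptamer, as the hairpin's guide strand may also repress RNAs that match its seed. AAACAAA was in 47 of them against 24.8 expected with 3' UTR length held (Bonferroni p over 16322 heptamers = 1.53e-05) and 27.8 with length and A content held (0.000992). The A content of the whole 3' UTR (median 27.7% against 26.4%), held in classes, thus does not account for it. Such classes do not hold local runs of A, so these stay open. Genes higher after knockdown did not have it in excess (14 of 102, 22.1 expected, exact hypergeometric p = 0.993), and among uncalled genes the 3715 with it lay 0.028 log2 units lower than the 8999 without (difference -0.028, SE 0.00544), at rank 1 of 16322 from the lowest heptamer (ranks 7, 2 and 86 in Dim, Int and Bright). The heptamer was picked and tested on the same libraries, genes are not independent, overlapping A-rich heptamers also passed (AAAACAA and AACAAAA), and the hairpin's sequence is not given in the sources used here. An off-target effect of the hairpin on part of the lower genes, among them Gnaq, Selp, Hnrnpa0 and Chek2, is thus a candidate explanation that the hairpin's sequence could decide, while other lower genes, such as Spp1, lack the heptamer.

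Other splits of the same libraries into groups of the same sizes were refitted. The real split was the only 1 of 35 with as many genes for reporter Bright against Dim (5254, highest other 1), Int against Dim (1189, highest other 0), and Bright against Int (1238, highest other 1). The same held for knockdown in Int (4, highest other 1), and it was the only 1 of 100 drawn for the mean knockdown effect (192, highest other 1). Shares of 1 of 35 and 1 of 100 are the smallest possible here. They speak against chance assignment only if libraries can be exchanged across letters. Each letter had the same sex in every group of an experiment. Only 8 of each 35 splits part all letters, too few for a share under 0.05. The 100 splits drawn did not hold the letters, which pair the Bright groups within the mean effect. The small count in Int is also not stable, since a fit of these groups alone (edgeR) called 0 genes (983 at an unadjusted p under 0.05). For knockdown in Bright the real split was also the only 1 of 35 (11, highest other 2), but there the letters pair the libraries, and the 8 splits that part all pairs (highest other 2) are too few for a share under 0.05. For knockdown in Dim all 35 splits, and for the difference between fractions all 100, gave as many as the real 0 genes, an outcome that a real count of 0 fixes, so it says nothing about chance. For cultured Bright against Dim 2 of 35 splits gave at least 3127 genes. The other split gave 3161 and put Bright shControl D with the 3 Dim libraries. The letters pair these libraries too, and the 8 splits that part as many pairs (highest other 579) are again too few for a share under 0.05.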
